A study of Homo sapiens with 120 samples.

How the data were processed

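RNA sequencing was performed on 120 libraries from established human cancer cell lines, and the deposited table gives 1 value per gene and library. Per the labels' protocols, cells were grown in 6-well plates and treated for 16 h, polyadenylated RNA was made into libraries with 14 cycles of PCR, and single-end reads of 75 nucleotides were collected on a NextSeq 500. The submitters' processing notes name Salmon 0.14 for quantification, DESeq2 1.30 and the genome build GRCh38.p12 (hg38). The annotation release was not given in the sources used here. Each deposited value is a signal in the form of a normalised read count: the authors divided the reads assigned to a gene by a size factor of the library. Dividing each library's values by its smallest step gave whole numbers for 100.0% of values at a tolerance of 0.01, a check that applied to 118 of the 120 libraries, so the reads behind the values could be recovered. The annotation used to place genes was GENCODE v29 on GRCh38. It held 96.7% of the 34073 deposited gene identifiers, and 99.6% of them (33933) had a symbol. Every data column was matched to 1 sample by its title, and 0 columns were left unmatched.

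The recovered depth ranged from 7.37 to 60.6 M reads (M, megareads) per library, with a median of 24.9 M reads. PCR reads without molecular identifiers are not independent molecules, so recovered depth describes counting error only. The labels give 3 replicate wells for each combination of prostate line and treatment. They do not say that wells came from separate cultures, so p-values there measure only the spread between these wells, which may be technical. Among the 72 replicate pairs the chi-square per degree of freedom over genes was at least 11.2, and no pair was treated as a repeated library. The 12 non-prostate lines had 1 library per line and treatment, and there the cell line was the replicate.

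The values were tested on the scale log2(normalised count + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend, two-sided), after removing genes with a mean below 10. Fold changes on this scale understate the change of genes with few reads. For the 4 prostate lines a single model held 24 line-by-treatment groups and 16794 genes, and each contrast was averaged with equal weight over the lines and then read in each line alone. For the 12 non-prostate lines the model held line and treatment and 17758 genes. P-values were adjusted over all genes of a contrast by the Benjamini-Hochberg method, and 0.05 was the threshold. In the text, "rose" and "fell" are used for genes and lists that passed it, and errors after ± are standard errors unless an SD is named. A count test was not the primary test because the deposited values are normalised. The recovered reads were tested with edgeR 4.0.16 (quasi-likelihood) as an alternative that was chosen after the values had been seen.

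The design, the contrasts, 27 gene lists and the rule for naming genes were fixed before the data were examined. The lists hold 713 genes, of which 709 were matched to the table. A gene was named if it was a drug target or pathway gene (PLK1, AR, CYP17A1). It was also named if it was among the 10 largest rises or the 10 largest falls of an averaged contrast past the threshold, with 1 sign in all 4 lines and a mean of at least 50. For an interaction the limit was 5 in each direction, and for abiraterone or onvansertib in a single prostate line it was 3. For the non-prostate lines 1 sign in at least 10 of 12 lines was required. The 4 members with the smallest p of each list and contrast were named too. Genes without a symbol, XIST and Y-linked genes were left out. Lists were tested with limma's fry, adjusted over all lists and contrasts of a model, and again with camera and an estimated correlation between genes. The fry p depends on the basis chosen for the residuals, and the basis of the default routine changed with the computer. It was therefore fixed in sample order after the results had been seen. List calls near the threshold can depend on this choice, and with it ribosomal protein genes with enzalutamide (adjusted p = 0.053) and p53 targets in the difference of abiraterone and enzalutamide (adjusted p = 0.052), called before, no longer passed. The fry p asks whether the members of a list move, on balance, in 1 direction, and compares the list neither with other genes nor with other lists. Differences between the 4 prostate lines in the abiraterone effect on a list were tested with limma's F test on the mean log2 value of its members in each library. Prostate and non-prostate lines were compared with an exact two-sided permutation test over 1820 arrangements, which cannot give a p below 0.00055.

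Alternatives were pseudocounts of 0.5 and 5, no filter, a filter at a mean of 50, rescaling by median ratios, quantile normalisation, robust moderation, the replicate number as a term, cell lines as replicates and the omission of each replicate number, library or cell line. Alternatives without 7 or 9 libraries that stood apart from their groups were added after the data had been seen. On simulated data with 200 changed genes, limma recovered 74.6%, 85.1% and 100.0% of changes of 1.5, 2 and 4 fold in the averaged abiraterone contrast. The figures were 41.8%, 62.7% and 87.9% for abiraterone in C4-2 alone, 64.2%, 73.1% and 92.4% for the interaction of abiraterone and onvansertib, and 52.2%, 71.6% and 87.9% in the non-prostate lines. Fits used the R package data.table (version 1.17.8), and tables and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Read-through genes, pseudogenes, members of near-identical families and antisense genes are reported as uncertain, since strand-aware counting was not stated and reads can be split between such genes.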

Results

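Transcript levels were measured by RNA sequencing in 4 prostate cancer lines and 12 cancer lines of other origin after 16 h of treatment. The drugs were abiraterone, an inhibitor of the androgen-synthesis enzyme CYP17A1, enzalutamide, an antagonist of the androgen receptor, and onvansertib, an inhibitor of the mitotic kinase PLK1. The prostate lines were LNCaP, which depends on androgen, and the castration-resistant lines C4-2, 22Rv1 and LNCaP95, of which 22Rv1 and LNCaP95 carry the AR-v7 splice variant of the receptor. Each prostate line received DMSO, each drug alone, abiraterone plus onvansertib or enzalutamide plus onvansertib, with 3 libraries per line and treatment and 72 libraries in all. Abiraterone was given at 5 uM (10 uM in LNCaP95), enzalutamide at 10 uM (20 uM in LNCaP95) and onvansertib at 15 nM in C4-2 and LNCaP95, 20 nM in 22Rv1 and 30 nM in LNCaP. The other lines were the leukaemia lines MV4-11 and OCI-AML-3 and the lines Cal-33, KYSE-450, SK-OV-3, OAW28, AU565, HCC1954, PSN-1, Panc1005, NCIH661 and Calu3. Each of them had 1 library for DMSO, abiraterone (2.5 to 10 uM), onvansertib (15 to 75 nM) and the combination, so single lines there have no replicate check. Depth ran from 13.2 to 23.9 M reads (M, megareads) per library in C4-2, from 7.37 to 18.6 M reads in LNCaP and from 11.3 to 60.6 M reads in 22Rv1. It ran from 20.4 to 37.2 M reads in LNCaP95 and from 15.2 to 50.2 M reads in the other lines. Values given after gene names are log2 fold changes ± standard error, averaged over the 4 prostate lines (n = 3 per line and treatment) unless a line is named, and coordinates are those of GRCh38. A count of lines beside a gene or value gives the lines with that sign, not calls in each line.

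PLK1 (ENSG00000166851.15, chromosome 16, 23677656 to 23690367), the target of onvansertib, rose with onvansertib in C4-2 (0.41 ± 0.058, adjusted p = 4.6e-06), LNCaP (0.68 ± 0.058, adjusted p = 6.7e-12) and 22Rv1 (0.42 ± 0.058, adjusted p = 1.3e-07), and its value in LNCaP95 was -0.04 ± 0.058 (adjusted p = 1). Averaged over the lines, PLK1 rose by 0.36 ± 0.029 with onvansertib (adjusted p = 4.3e-14) and fell by 0.13 ± 0.029 with enzalutamide (adjusted p = 6e-04). With abiraterone its value was -0.07 ± 0.029 (adjusted p = 0.068), which passed the threshold at -0.08 without LNCaP abiraterone replicate 3 or LNCaP95 abiraterone replicate 3 and at -0.09 without 22Rv1 DMSO replicate 2. AR (ENSG00000169083.18, chromosome X, 67544032 to 67730619), which encodes the androgen receptor, had DMSO means of 12350 ± 243 normalised reads in C4-2, 14660 ± 717 in LNCaP, 20930 ± 1010 in 22Rv1 and 16660 ± 262 in LNCaP95 (SD, n = 3). AR fell with abiraterone in C4-2 (-0.33 ± 0.06, adjusted p = 0.00012) and LNCaP (-0.42 ± 0.06, adjusted p = 1e-06), while the values were -0.02 in 22Rv1 (adjusted p = 0.91) and -0.18 in LNCaP95 (adjusted p = 0.21). With enzalutamide AR fell in C4-2 (-0.38 ± 0.06, adjusted p = 6.6e-06) and LNCaP (-0.26 ± 0.06, adjusted p = 0.0021). CYP17A1, the target of abiraterone, was below the expression filter in both sets of lines, so no fold change is given for it. In the non-prostate lines PLK1 had values of -0.02 ± 0.055 with abiraterone (adjusted p = 0.91) and 0.14 ± 0.055 with onvansertib (adjusted p = 0.6), and rose with the combination (0.30 ± 0.055, adjusted p = 0.00062, higher in 11 of 12 lines).

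Abiraterone was set against DMSO to find the transcripts that responded to it within the 16 h of treatment. Androgen receptor target genes fell: 31 of 38 measured members fell, 0 rose and 7 did not pass, with 33 lower when adjusted over the list alone (median -0.49, adjusted p = 3.4e-40). The prostate homeobox gene NKX3-1 (chromosome 8, 23678693 to 23682927) fell by 1.44 ± 0.026 (adjusted p = 7.4e-43), and the kallikrein gene KLK2 (chromosome 19, 50861568 to 50880567) fell by 1.48 ± 0.092 (adjusted p = 8.7e-19). SLC45A3, a solute carrier of the prostate epithelium (chromosome 1, 205657851 to 205680459), fell by 1.42 ± 0.057. PMEPA1 (-1.31 ± 0.093), the zinc finger gene ZBTB16 (-1.31 ± 0.223) and the FK506-binding protein gene FKBP5 (-0.95 ± 0.024) fell with it. The androgen-glucuronidating enzyme gene UGT2B28 (-1.60 ± 0.201, adjusted p = 2e-08) and the nicotinic receptor subunit gene CHRNA2 (-2.86 ± 0.261, adjusted p = 1.4e-12) also fell, each with that sign in all 4 lines. Cholesterol biosynthesis and SREBP2 target genes fell, with 23 of 28 lower and 0 higher (25 adjusted over the list alone, median -0.45, adjusted p = 1.4e-29). The squalene synthase gene FDFT1 fell by 0.72 ± 0.022 (adjusted p = 1.6e-32), as did the sterol sensor gene INSIG1 (-0.84 ± 0.028) and the isoprenoid isomerase gene IDI1 (-0.60 ± 0.031). Among fatty acid synthesis and SREBP1 target genes 8 of 19 fell and 1 rose (9 and 2 adjusted over the list alone, adjusted p = 2.3e-19). The desaturase gene FADS2 fell by 0.53 ± 0.027 (lower in all 4 lines), and SCD (-0.38 ± 0.023) had the same sign in 3 of them.

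Several stress-related groups moved with abiraterone in opposite directions. Integrated stress response genes rose, with 25 of 36 higher and 1 lower (28 and 1 adjusted over the list alone, median 0.22, adjusted p = 9.1e-18). The cystine transporter gene SLC7A11 rose by 0.71 ± 0.042 (adjusted p = 1.4e-19), the transcription factor gene ATF4 by 0.34 ± 0.025 and the serine synthesis gene PSAT1 by 0.28 ± 0.023. Endoplasmic reticulum unfolded protein response genes fell on balance, with 12 of 29 lower and 2 higher (14 and 2 adjusted over the list alone, adjusted p = 1.1e-18). The chaperone gene HSPA5 (-0.33 ± 0.019) and MANF (-0.24 ± 0.032) fell, each with that sign in 3 lines. Among p53 target genes 11 of 33 rose and 0 fell (11 adjusted over the list alone, adjusted p = 2.1e-16), with BTG2 at 0.47 ± 0.037, the cell cycle inhibitor gene CDKN1A at 0.43 ± 0.051 and GDF15 at 1.01 ± 0.147. DNA replication and G1/S genes fell, with 18 of 52 lower and 1 higher (18 and 1 adjusted over the list alone, adjusted p = 1.6e-11). The uracil glycosylase gene UNG (-0.28 ± 0.042) and the helicase subunit gene MCM2 (-0.28 ± 0.046) fell. Hypoxia and glycolysis genes fell on balance (12 of 29 lower and 2 higher, 14 and 2 adjusted over the list alone, adjusted p = 2.5e-11), with the lactate dehydrogenase gene LDHA at -0.29 ± 0.028. Apoptosis regulators rose on balance (7 of 22 higher and 1 lower, 8 and 2 adjusted over the list alone, adjusted p = 1.6e-07), with the BH3-only gene BMF at 0.93 ± 0.089 and BCL2L1, which encodes an anti-apoptotic protein, at -0.23 ± 0.044. Luminal prostate lineage markers fell, with 10 of 14 lower and 0 higher (10 and 1 adjusted over the list alone, adjusted p = 2.2e-35), and the prostate-specific antigen gene KLK3 fell by 1.10 ± 0.063.

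Other groups passed the rotation test for abiraterone but not the test with an estimated correlation. LXR and cholesterol efflux genes rose (3 of 9, also 3 adjusted over the list alone, adjusted p = 1.1e-07, adjusted p = 0.084 with an estimated correlation), led by the sterol transporter gene ABCG1 (0.90 ± 0.081) and MYLIP (0.45 ± 0.045). Aryl hydrocarbon and pregnane X receptor target genes rose (4 of 10, 5 higher and 1 lower adjusted over the list alone, adjusted p = 3e-06, adjusted p = 0.061 with an estimated correlation), with the monooxygenase gene CYP1A2 at 2.15 ± 0.328. Interferon-stimulated genes rose on balance (5 of 31 higher and 0 lower, 7 and 1 adjusted over the list alone, adjusted p = 1.2e-07, adjusted p = 0.098 with an estimated correlation), with STAT2 at 0.32 ± 0.044. Cytosolic heat shock genes fell (5 of 18 lower and 1 higher, 7 and 1 adjusted over the list alone, adjusted p = 0.0038, adjusted p = 0.16 with an estimated correlation), with DNAJB1 at -0.16 ± 0.038. Mitotic spindle genes rose on balance (11 of 58 higher and 2 lower, 11 and 3 adjusted over the list alone, adjusted p = 0.012, adjusted p = 0.44 with an estimated correlation), and that call was lost at an adjusted p of 0.096 after median-ratio rescaling. KIF14, a mitotic kinesin gene, rose by 0.26 ± 0.039. Cytoskeleton genes fell (8 of 23, also 8 adjusted over the list alone, adjusted p = 8.4e-05, adjusted p = 0.093 with an estimated correlation), with the tubulin gene TUBA1C at -0.19 ± 0.027. Cytosolic ribosomal protein genes fell (14 of 37, 22 adjusted over the list alone, adjusted p = 0.0013, adjusted p = 0.17 with an estimated correlation), and after quantile normalisation RPL14 and RPL27 no longer passed. The lists for NRF2 (adjusted p = 0.098), steroid metabolism (0.069), NF-kB (0.53), immediate early genes (0.51), lysosome (0.17) and the neuroendocrine (0.42), blood (0.87), fibroblast (0.32), squamous (0.27) and mitochondrially encoded groups (0.97) did not pass. The steroid list passed downward after median-ratio rescaling (0.019) and without 9 libraries that stood apart (0.028), and the NRF2 list passed upward without the 9 (0.027).

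With abiraterone, 3084 of 16794 genes passed the threshold, 1632 higher and 1452 lower, and 120 of them changed by at least 2 fold. Other rises that had the same sign in all 4 lines were in PLEKHH2 (1.91 ± 0.339, adjusted p = 3e-05), the actin regulator gene NHS (1.57 ± 0.314), the transporter gene SLC6A20 (1.42 ± 0.359), TINAGL1 (1.27 ± 0.291) and the growth factor receptor gene FGFR2 (1.23 ± 0.226). Falls of the same kind were in the mitochondrial transhydrogenase gene NNT (-1.62 ± 0.263), DOCK8 (-1.55 ± 0.39) and the von Willebrand factor gene VWF (-1.45 ± 0.32). The rise of the multicopy pseudogene ANKRD20A5P (1.68 ± 0.372) is uncertain because its reads can be shared with copies. When the 4 line means served as replicates, in place of wells, 18 genes passed.

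Enzalutamide was compared with DMSO in the same way, as a drug acting on the receptor itself. Its known targets fell, with 34 of 38 androgen receptor target genes lower and 0 higher (34 adjusted over the list alone, median -0.63, adjusted p = 2.7e-41). NKX3-1 fell by 1.57 ± 0.026 (adjusted p = 1e-44) and C1orf116 (chromosome 1, 207018521 to 207032756) fell by 1.39 ± 0.025. FKBP5 (-1.08 ± 0.024) and UGT2B28 (-2.09 ± 0.201) fell as well. Luminal prostate lineage markers fell too, with 10 of 14 lower and 2 higher (10 and 3 adjusted over the list alone, adjusted p = 1.4e-34). Cholesterol biosynthesis and SREBP2 target genes fell, with 18 of 28 lower and 0 higher (18 and 1 adjusted over the list alone, median -0.14, adjusted p = 8.8e-10). DHCR24, which encodes the last reductase of the pathway and is also an androgen target, fell by 0.54 ± 0.048. FDFT1 (-0.26 ± 0.022) and INSIG1 (-0.21 ± 0.028, 3 of 4 lines) fell less. Fatty acid synthesis genes fell on balance (7 of 19 lower and 2 higher, 7 and 3 adjusted over the list alone, adjusted p = 7e-08), with the elongase gene ELOVL5 at -0.52 ± 0.033. Integrated stress response genes rose, with 28 of 36 higher and 0 lower (32 adjusted over the list alone, adjusted p = 1.2e-21). SLC7A11 rose by 0.56 ± 0.042, and the asparagine synthetase gene ASNS (0.51 ± 0.037) and PSAT1 (0.40 ± 0.023) rose with the same sign in 3 lines.

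Unfolded protein response genes fell with enzalutamide, with 12 of 29 lower and 1 higher (13 and 3 adjusted over the list alone, adjusted p = 5.7e-22), among them HSPA5 (-0.44 ± 0.019) and MANF (-0.40 ± 0.032), both in 3 of 4 lines. Cytosolic heat shock genes fell (11 of 18 lower, 13 adjusted over the list alone, adjusted p = 6.2e-08), with HSPH1 at -0.36 ± 0.074. DNA replication genes fell (17 of 52 lower and 0 higher, 20 and 1 adjusted over the list alone, adjusted p = 3.2e-12), with the ribonucleotide reductase gene RRM2 at -0.24 ± 0.04. Hypoxia and glycolysis genes fell (9 of 29 lower and 2 higher, 12 and 2 adjusted over the list alone, adjusted p = 8e-12), with LDHA at -0.34 ± 0.028. Among p53 target genes 8 of 33 rose and 1 fell (9 and 1 adjusted over the list alone, adjusted p = 1.7e-13), with TP53INP1 at 0.38 ± 0.036. Calls lost with an estimated correlation were those for mitotic spindle genes (down, 8 of 58 lower and 2 higher, adjusted p = 0.21 with an estimated correlation), LXR genes (up, 3 of 9, 0.34) and cytoskeleton genes (down, 7 of 23, 0.092). Interferon-stimulated genes (up, 4 higher and 3 lower of 31, 0.58) and apoptosis regulators (up, 3 of 22 higher and 1 lower, 0.3) also belonged here, and these counts were the same adjusted over the list alone. So did steroid metabolism genes (down, 2 of 15 lower and 1 higher, 4 and 4 adjusted over the list alone, 0.3). Ribosomal protein genes did not pass as a list (8 of 37 lower, 13 adjusted over the list alone, adjusted p = 0.053), though the list passed after median-ratio rescaling (0.02) and without 9 libraries that stood apart (0.039). After quantile normalisation RPL19 (0.03) and RPS11 (0.01) pointed the other way. In all, 2510 genes passed, 1316 higher and 1194 lower. Rises with the same sign in all 4 lines included PLEKHH2 (1.52 ± 0.339), the hyaluronidase gene CEMIP (1.46 ± 0.383) and the exchange factor gene VAV3 (1.12 ± 0.252), and falls included NPNT (-1.79 ± 0.426), the Hippo pathway coactivator gene WWTR1 (-1.74 ± 0.273) and GRIN3A (-1.42 ± 0.214). Values for the read-through genes NPHP3-ACAD11 (2.85 ± 0.847) and BIVM-ERCC5 (-4.54 ± 1.235) are uncertain. With line means as replicates limma called 0 genes.

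A direct comparison of abiraterone with enzalutamide asked where the responses to these drugs differed. Cholesterol biosynthesis and SREBP2 target genes were lower with abiraterone, with 21 of 28 lower and 0 higher (24 adjusted over the list alone, median -0.30, adjusted p = 7e-23). INSIG1 (chromosome 7, 155297776 to 155310235) differed by -0.63 ± 0.028 (adjusted p = 7e-24), FDFT1 by -0.46 ± 0.022 and the synthase gene HMGCS1 (chromosome 5, 43289395 to 43313512) by -0.53 ± 0.036. The demethylase gene MSMO1 (-0.50 ± 0.046), the decarboxylase gene MVD (-0.77 ± 0.136), the cyclase gene LSS (-0.49 ± 0.106) and IDI1 (-0.49 ± 0.031) were lower as well, each with that sign in all 4 lines. Genes of fatty acid synthesis were lower (4 of 19, 8 adjusted over the list alone, adjusted p = 1.5e-10), with SCD at -0.26 ± 0.023 in 3 lines. The endothelial lipase gene LIPG (-1.40 ± 0.25) and the oestrogen receptor gene GPER1 (-0.74 ± 0.178) were lower with abiraterone, and AKAP12 (0.89 ± 0.187), UGT2B11 (0.66 ± 0.107) and the clock gene PER1 (0.50 ± 0.119) were higher. Mitotic spindle genes were higher on balance with abiraterone (6 of 58, 17 adjusted over the list alone, adjusted p = 5.5e-07), with KIF14 at 0.19 ± 0.039. Aryl hydrocarbon and pregnane X receptor target genes were higher (2 of 10, 3 adjusted over the list alone, adjusted p = 4.8e-06), with TIPARP at 0.29 ± 0.057. Targets of the androgen receptor differed little, with 3 of 38 higher (6 higher and 1 lower adjusted over the list alone, median 0.02, adjusted p = 0.018, adjusted p = 0.17 with an estimated correlation). Among them was C1orf116 (0.24 ± 0.025), and the list call was lost at an adjusted p of 0.07 without 9 libraries that stood apart. AR itself differed by -0.07 ± 0.03 (adjusted p = 0.21). Calls lost with an estimated correlation were those for LXR genes (up, 2 of 9, adjusted p = 0.16 with an estimated correlation), heat shock genes (up, 5 of 18, 0.084), apoptosis regulators (up, 1 of 22, 0.15) and fibroblast markers (up, 1 of 6, 0.15), with the same counts adjusted over the list alone. They also included integrated stress response genes (down, 6 of 36 lower and 1 higher, 11 and 1 adjusted over the list alone, 0.15), unfolded protein response genes (up, 3 of 29, 3 higher and 2 lower adjusted over the list alone, 0.22) and interferon-stimulated genes (up, 1 higher and 1 lower of 31, 1 and 2 adjusted over the list alone, 0.16). Targets of p53 did not pass (2 of 33 higher, also 2 adjusted over the list alone, adjusted p = 0.052), though they did with the replicate number as a block (0.043), after median-ratio rescaling (0.034) and without the 9 libraries (0.0015). In all, 491 genes passed, 239 higher and 252 lower. The count was 312 without LNCaP95 abiraterone replicate 3, 1195 with a term for 7 libraries that stood apart, and 0 by limma with line means as replicates.

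Onvansertib, compared with DMSO, was followed by a rise of mitotic spindle and chromosome segregation genes, the group that includes its target. Of 58 members 46 rose, 2 fell and 10 did not pass (51 higher and 2 lower adjusted over the list alone, median 0.33, adjusted p = 2.3e-25). The kinesin genes KIF18A (0.61 ± 0.04) and KIF14 (0.55 ± 0.039), the cyclin gene CCNB1 (0.41 ± 0.028) and the mitotic kinase gene AURKA (0.51 ± 0.036) rose, each with that sign in all 4 lines. In single lines AURKA rose by 0.67 ± 0.071 in C4-2, 0.68 in LNCaP, 0.35 in 22Rv1 and 0.35 in LNCaP95. Its call in LNCaP95 was lost without DMSO replicate 2 or 3 (adjusted p = 0.15 each) or onvansertib replicate 3 (adjusted p = 0.12). DNA replication genes fell on balance, with 16 of 52 lower and 2 higher (17 and 4 adjusted over the list alone, adjusted p = 1.7e-06). UNG (-0.35 ± 0.042) and the helicase loader gene MCM10 (-0.20 ± 0.037, 3 lines) fell, while the replication factor gene RFC3 (0.15 ± 0.028) and the origin recognition gene ORC6 (0.24 ± 0.045, 3 lines) rose. The androgen receptor target list fell on balance, with 11 of 38 lower and 0 higher (11 adjusted over the list alone, median -0.07, adjusted p = 2.5e-06) and NKX3-1 at -0.18 ± 0.026. Hypoxia and glycolysis genes fell (9 of 29 lower and 1 higher, 10 and 1 adjusted over the list alone, adjusted p = 9.7e-12), with the aldolase gene ALDOA at -0.28 ± 0.04 in 3 lines. Fatty acid synthesis genes fell (5 of 19 lower, 6 adjusted over the list alone, adjusted p = 2.7e-08), with FADS2 at -0.22 ± 0.027. Unfolded protein response genes fell (7 of 29 lower, also 7 adjusted over the list alone, adjusted p = 6.5e-08), with the transcription factor gene XBP1 at -0.17 ± 0.024. Luminal markers fell (3 of 14, also 3 adjusted over the list alone, adjusted p = 0.00013).

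Further onvansertib calls did not hold with an estimated correlation. Integrated stress response genes fell (9 of 36 lower and 2 higher, 11 and 2 adjusted over the list alone, adjusted p = 0.17 with an estimated correlation), with DDIT4 at -0.19 ± 0.035 in 3 lines. Lysosome genes fell (9 of 28, 11 lower and 1 higher adjusted over the list alone, 0.093 with an estimated correlation), with the cathepsin gene CTSZ at -0.16 ± 0.027. NRF2 genes fell (4 of 22, 6 adjusted over the list alone, 0.21) and p53 targets rose (2 of 33, 0 adjusted over the list alone, 0.4). Immediate early genes fell (2 of 22, 0.16), among them MYC (-0.22 ± 0.04) and JUND (-0.25 ± 0.052). Cytoskeleton genes (6 of 23 lower, 0.12), steroid metabolism genes (2 of 15 lower, 0.13), interferon-stimulated genes (1 higher and 1 lower of 31, 0.47) and fibroblast markers (1 of 6 lower, 0.33) fell on balance. The last 5 lists had the same counts adjusted over the list alone, and TUBA1C (-0.26 ± 0.027) and VIM (-0.23 ± 0.051) were among their members that fell. Ribosomal protein genes fell by the rotation test, with 20 of 37 lower (32 adjusted over the list alone, adjusted p = 7.7e-05, adjusted p = 0.074 with an estimated correlation), and RPL14 and RPL19 no longer passed after quantile normalisation. Cholesterol biosynthesis genes did not pass as a group (3 higher and 3 lower of 28, adjusted p = 0.49), nor did the lists for LXR, heat shock, aryl hydrocarbon receptor, NF-kB or apoptosis. In all, 2340 genes passed (4530 in 22Rv1 alone, 13 to 218 in other lines), 1206 higher and 1134 lower, and 70 changed by at least 2 fold. The higher ones included GOLGA8B (1.32 ± 0.162), nearly identical to GOLGA8A, the pseudogene SMG1P3 (1.16 ± 0.098) and the read-through gene BMS1P4-AGAP5 (3.63 ± 0.868), all uncertain. The fall of MT1G (-0.79 ± 0.209), from the family of similar metallothionein genes, is uncertain too. The ethanolamine kinase gene ETNK2 (-0.87 ± 0.261) and CARMIL2 (-0.69 ± 0.17) fell, and RNF207 rose (1.61 ± 0.324), the last without passing in edgeR. With line means as replicates 1 gene passed.

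Abiraterone plus onvansertib, compared with DMSO, moved most of the groups that moved with the single drugs. Mitotic spindle genes rose, with 48 of 58 higher and 1 lower (48 and 1 adjusted over the list alone, median 0.39, adjusted p = 1.8e-29), with AURKA at 0.72 ± 0.036 and CCNB1 at 0.56 ± 0.028. Genes driven by the androgen receptor fell, with 29 of 38 lower (30 lower and 1 higher adjusted over the list alone, median -0.59, adjusted p = 3.4e-40), NKX3-1 at -1.44 ± 0.026 and PMEPA1 at -1.57 ± 0.093. Cholesterol biosynthesis genes fell, with 22 of 28 lower and 1 higher (23 and 1 adjusted over the list alone, median -0.44, adjusted p = 2.4e-29), INSIG1 at -0.93 ± 0.028 and the squalene epoxidase gene SQLE at -0.71 ± 0.035. Fatty acid synthesis genes fell (9 of 19 lower, also 9 adjusted over the list alone, adjusted p = 8.6e-25), with SCD at -0.61 ± 0.023. DNA replication genes fell, with 24 of 52 lower and 5 higher (26 and 6 adjusted over the list alone, adjusted p = 1.1e-17), UNG at -0.60 ± 0.042 and the licensing factor gene CDC6 at -0.44 ± 0.04. Genes of the integrated stress response rose (25 of 36 higher and 1 lower, 25 and 2 adjusted over the list alone, adjusted p = 6.3e-17), with ATF4 at 0.41 ± 0.025. Targets of p53 rose (9 of 33 higher and 1 lower, the same adjusted over the list alone, adjusted p = 1.3e-16), with CDKN1A at 0.58 ± 0.051. Unfolded protein response genes fell (15 of 29 lower and 1 higher, 17 and 1 adjusted over the list alone, adjusted p = 9.8e-24). Hypoxia and glycolysis genes (12 of 29 lower and 2 higher, 13 and 2 adjusted over the list alone, adjusted p = 2e-15) and luminal markers (9 of 14 lower, 10 lower and 1 higher adjusted over the list alone, adjusted p = 6.2e-35) fell too. AR fell in C4-2 (-0.73 ± 0.06, adjusted p = 5.8e-14), LNCaP (-0.60 ± 0.06, adjusted p = 5.2e-11) and LNCaP95 (-0.31 ± 0.06, adjusted p = 0.00083).

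For this combination several calls did not hold with an estimated correlation. Aryl hydrocarbon receptor targets rose (3 of 10, also 3 adjusted over the list alone, adjusted p = 0.078 with an estimated correlation), and steroid metabolism genes fell (7 of 15 lower and 1 higher, 8 and 1 adjusted over the list alone, 0.098), among them CYB5A. Apoptosis regulators rose (4 of 22 higher and 3 lower, 5 and 3 adjusted over the list alone, 0.42), as did interferon-stimulated genes (6 of 31 higher and 5 lower, the same adjusted over the list alone, 0.69). Lysosome genes fell (9 of 28 lower and 2 higher, 9 and 3 adjusted over the list alone, 0.31). In 3 lists median, mean and test differed in sign. LXR genes rose (3 of 9 higher and 1 lower, 0.33 with an estimated correlation) with a median of -0.01 and a mean of 0.15. NF-kB genes fell (1 of 12, 0.69 with an estimated correlation) with a median and a mean of 0.02. Cytoskeleton genes fell (8 of 23 lower and 3 higher, 0.35 with an estimated correlation) with a median of -0.03 and a mean of 0.02, and all 3 had the same counts adjusted over the list alone. Ribosomal protein genes fell (17 of 37, 18 adjusted over the list alone, adjusted p = 0.3 with an estimated correlation), and after quantile normalisation RPL14 (0.02), RPS11 (0.02) and RPL19 (0.08) were higher instead. NFKBIA, which encodes an NF-kB inhibitor, fell by 0.60 ± 0.038, and MYC fell by 0.36 ± 0.04. In all, 4796 genes passed, 2440 higher and 2356 lower, and 253 changed by at least 2 fold. Rises of the average with 1 sign in all 4 lines included PLEKHH2 (2.08 ± 0.339), CLHC1 (1.62 ± 0.338), the collagen gene COL27A1 (1.57 ± 0.368) and MYO1A (1.52 ± 0.427), and falls included CHRNA2 (-1.98 ± 0.261), UGT2B28 (-1.59 ± 0.201), the cytokine signalling suppressor gene SOCS2 (-1.05 ± 0.156) and HSPA2 (-1.07 ± 0.299). With line means as replicates 907 genes passed.

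Enzalutamide plus onvansertib gave a rise of mitotic spindle genes, with 47 of 58 higher and 3 lower (48 and 3 adjusted over the list alone, median 0.30, adjusted p = 8.6e-25), KIF18A at 0.63 ± 0.04 and AURKA at 0.46 ± 0.036. Genes under androgen receptor control fell (31 of 38 lower, 33 adjusted over the list alone, median -0.66, adjusted p = 2.7e-41). NKX3-1 (-1.66 ± 0.026, adjusted p = 6.1e-46), SLC45A3 (-1.69 ± 0.057) and PMEPA1 (-1.82 ± 0.093) were among them. DNA replication genes fell (28 of 52 lower and 1 higher, 32 and 3 adjusted over the list alone, adjusted p = 1.6e-21), UNG at -0.61 ± 0.042 and the epigenetic regulator gene UHRF1 at -0.41 ± 0.039. Cholesterol biosynthesis genes fell (17 of 28 lower, 19 lower and 2 higher adjusted over the list alone, adjusted p = 1e-12), with DHCR24 at -0.65 ± 0.048. Fatty acid synthesis genes fell (10 of 19 lower and 1 higher, the same adjusted over the list alone, adjusted p = 8.1e-18), with the synthase gene FASN at -0.63 ± 0.077. Integrated stress response genes rose (24 of 36, 29 adjusted over the list alone, adjusted p = 4.7e-18), with SLC7A11 at 0.73 ± 0.042. Targets of p53 rose (13 of 33 higher and 2 lower, 14 and 2 adjusted over the list alone, adjusted p = 2.2e-14), with PMAIP1 at 0.44 ± 0.078. Unfolded protein response genes (15 of 29 lower and 1 higher, 16 and 1 adjusted over the list alone, adjusted p = 6.4e-20) and hypoxia and glycolysis genes (13 of 29 lower and 2 higher, 15 and 2 adjusted over the list alone, adjusted p = 3.5e-16) fell. Steroid metabolism genes (5 of 15 lower, also 5 adjusted over the list alone, adjusted p = 8.8e-09) and luminal markers (10 of 14 lower and 2 higher, 11 and 3 adjusted over the list alone, adjusted p = 2.2e-35) fell too.

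Calls for this combination that did not hold with an estimated correlation were all downward. NFKBIA (-0.59 ± 0.038) and MYC (-0.35 ± 0.04) fell, from the NF-kB list (1 of 12, adjusted p = 0.34 with an estimated correlation) and the immediate early list (6 of 22, 0.3), with the same counts adjusted over the list alone. Lysosome genes (11 of 28 lower and 2 higher, 11 and 3 adjusted over the list alone, 0.26), cytoskeleton genes (10 of 23, 11 adjusted over the list alone, 0.061) and fibroblast markers (1 of 6, also 1 adjusted over the list alone, 0.56) fell. The fibroblast call was also lost with the replicate number as a block (0.052), without the 9 libraries (0.31) and with a term for 7 of them (0.15). Ribosomal protein genes fell (30 of 37, 31 adjusted over the list alone, 0.12 with an estimated correlation), with RPL19 not passing after quantile normalisation. In all, 4721 genes passed, 2243 higher and 2478 lower, and 167 changed by at least 2 fold, with SLC6A20 (1.72 ± 0.359), NHS (1.58 ± 0.314) and BNIPL (1.24 ± 0.305) among the rises. With line means as replicates 551 genes passed.

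**Figure D1:**
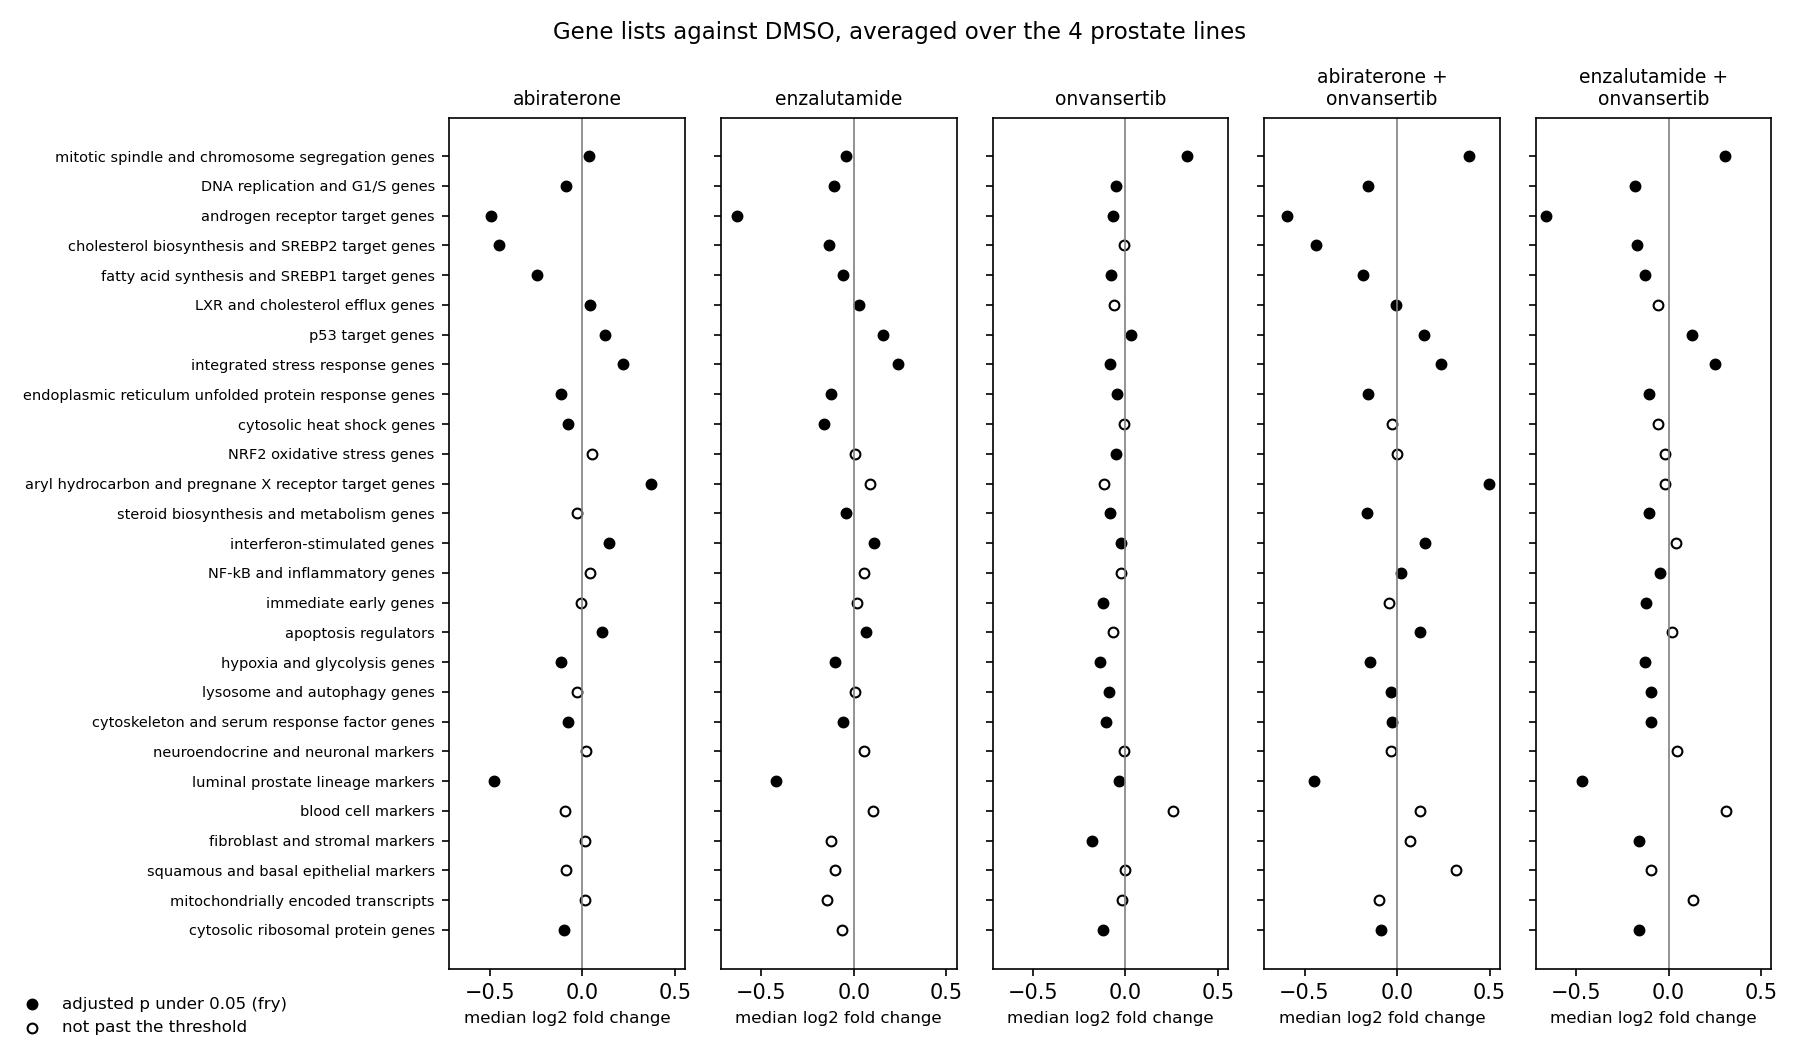
Median log2 fold change against DMSO of the members of each of the 27 gene lists, averaged over the 4 prostate lines, for the 5 treatments, with filled points where the list passed the rotation test at an adjusted p of 0.05. The androgen receptor target list sits at -0.49 with abiraterone and -0.63 with enzalutamide, and the mitotic spindle list sits at 0.33 with onvansertib and 0.39 with abiraterone plus onvansertib.

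Interaction terms asked whether a combination differed from the sum of the log2 effects of its single drugs. The term adds the DMSO mean to that of the combination and subtracts those of the single drugs. A shift shared by all treated groups of a line therefore enters it with the opposite sign. In 22Rv1, whose DMSO libraries lay below all treated ones in nuclear-retained transcripts, such a shift cannot be told apart from an interaction. For abiraterone and onvansertib 29 genes passed, 7 higher and 22 lower, a balance that was 13 and 10 without the 9 libraries and 45 and 47 without 7 of them. NKX3-1 had a positive term (0.19 ± 0.037, adjusted p = 0.011), and AURKA had 0.24 ± 0.05 (adjusted p = 0.019), both lost without the 9 libraries and after quantile normalisation. PAXBP1 had -0.61 ± 0.113, lost without the 9 libraries, and the pseudogene GTF2IP20 -0.67 ± 0.119, which is uncertain. The terms were positive on balance for androgen receptor targets (1 of 38, 5 adjusted over the list alone, adjusted p = 0.0013), hypoxia genes (0 of 29, 4 adjusted over the list alone, adjusted p = 0.00018), cytoskeleton genes (0 of 23, 5 adjusted over the list alone, adjusted p = 0.002), luminal markers (1 of 14, 3 adjusted over the list alone, adjusted p = 0.0032) and ribosomal protein genes (0 of 37, 18 adjusted over the list alone, adjusted p = 0.0051, adjusted p = 0.054 with an estimated correlation). Mitotic spindle genes did not pass as a group (adjusted p = 0.22), though they passed upward without the 9 libraries (0.0073) and with a term for 7 of them (0.0038), and PLK1 had 0.05 ± 0.041 (adjusted p = 0.62). The count of 29 depended on single libraries. Of 48 fits with 1 library left out, 23 moved it beyond 1.5 times, and it ran from 17 without 22Rv1 DMSO replicate 1 to 183 without 22Rv1 DMSO replicate 2. With line means as replicates limma called 0 genes.

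For enzalutamide and onvansertib 85 genes passed, 17 higher and 68 lower. The structure-specific endonuclease subunit gene EME2 had a term of -1.05 ± 0.206 (adjusted p = 0.0065). VWF (2.35 ± 0.453), AGR2 (0.41 ± 0.087) and UBE2D4 (0.26 ± 0.055) had positive terms that were lost without the 9 libraries. Terms were positive on balance for unfolded protein response genes (2 of 29, 5 adjusted over the list alone, adjusted p = 2.9e-06), heat shock genes (0 of 18, 8 adjusted over the list alone, adjusted p = 0.0015), hypoxia genes (0 of 29, 5 adjusted over the list alone, adjusted p = 0.00022), androgen receptor targets (0 of 38, 0 adjusted over the list alone, adjusted p = 0.0027) and luminal markers (0 of 14, 0 adjusted over the list alone, adjusted p = 0.039, adjusted p = 0.098 with an estimated correlation), the last call being lost without the 9 libraries (0.14). Among unfolded protein response genes HSPA5 had 0.18 ± 0.027 (adjusted p = 0.00046), lost after quantile normalisation. Mitotic spindle genes did not pass (adjusted p = 0.27). The count was 26 (11 higher and 15 lower) without the 9 libraries, 564 (282 higher) with a term for 7 of them and 0 with line means as replicates. Of 48 fits with 1 library left out, 11 moved it beyond 1.5 times, and it ran from 46 without C4-2 combination replicate 1 to 222 without 22Rv1 combination replicate 2.

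Within single prostate lines the androgen and stress genes moved to different extents. FKBP5 fell with abiraterone in C4-2 (-1.29 ± 0.048), LNCaP (-0.94) and 22Rv1 (-1.45), and its value in LNCaP95 was -0.14 (adjusted p = 0.22). CCDC141 (-5.96 ± 0.553, adjusted p = 6.7e-12) and SLC45A3 (-2.48 ± 0.114) fell and the glucose transporter gene SLC5A1 rose (3.04 ± 0.564, adjusted p = 0.00019) in C4-2. CHRNA2 (-4.13 ± 0.522) and KLK2 (-2.75 ± 0.184) fell in LNCaP, and the orphan receptor gene GPR157 fell in 22Rv1 (-2.67 ± 0.641, adjusted p = 0.0015, or 0.069 in a separate fit of this line). In LNCaP95 the glutathione-degrading enzyme gene CHAC1 (1.47 ± 0.194) and BEST1 (1.35 ± 0.191) rose, while TXNIP (-0.97 ± 0.054) and INSIG1 (-0.97 ± 0.056) fell. With onvansertib the semaphorin gene SEMA6A fell in C4-2 (-1.19 ± 0.242, adjusted p = 0.0026, or 0.18 in a separate fit of this line) and the Wnt effector gene TCF7L2 fell in LNCaP (-2.95 ± 0.432). In every treatment some genes passed in the same direction in all 4 lines: 3 up and 9 down with abiraterone, 2 and 3 with enzalutamide, 4 and 0 with onvansertib, 25 and 30 with abiraterone plus onvansertib, and 20 and 23 with enzalutamide plus onvansertib. Genes called in opposite directions in different lines numbered 95, 469, 22, 160 and 244 in the same order.

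Libraries that stood apart from their groups were found in 3 of the prostate lines. In 7 libraries ITGB1P1, a processed pseudogene of the integrin gene ITGB1, was listed at 0, while the other 65 prostate libraries had between 127.6 and 545.7 normalised reads. They were 22Rv1 onvansertib replicates 2 and 3 and enzalutamide-onvansertib replicate 1, and LNCaP95 abiraterone replicate 3, enzalutamide replicate 2 and enzalutamide-onvansertib replicates 2 and 3. Under a term for these 7 libraries 6410 genes differed from the rest of their groups, 2985 higher and 3425 lower, and ITGB1 was higher by 0.83 (adjusted p = 1.5e-13). LNCaP95 onvansertib replicate 3 held 22Rv1 marker transcripts at a median of 1.57% of their 22Rv1 level, and LNCaP abiraterone replicate 2 was the last of the 9 libraries. Without the 9 libraries 8 list calls were lost, and 17 were gained. Those lost included interferon-stimulated genes with onvansertib (adjusted p = 0.072), with abiraterone plus onvansertib (0.099) and in the difference of abiraterone and enzalutamide (0.06), fibroblast markers with onvansertib (0.06) and immediate early genes with enzalutamide plus onvansertib (0.071). Those gained included heat shock genes with abiraterone plus onvansertib (down, 0.0047) and, with enzalutamide plus onvansertib, heat shock genes (down, 1.5e-05), LXR genes (up, 0.0033) and apoptosis regulators (up, 0.0029). In 22Rv1 a set of 20 nuclear-retained transcripts had higher medians in each treated group than in DMSO, from 0.66 with abiraterone to 1.04 with enzalutamide plus onvansertib.

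**Figure D2:**
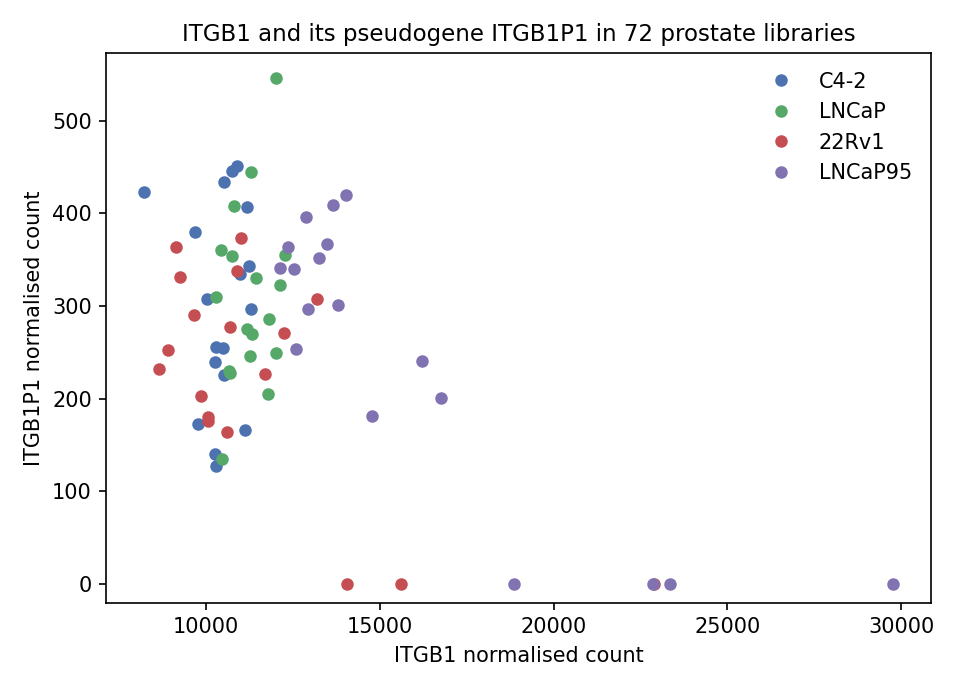
Normalised read count of ITGB1P1 against that of ITGB1 in each of the 72 prostate libraries, coloured by cell line. The 7 libraries at 0 for ITGB1P1 belong to 22Rv1 and LNCaP95, and the other 65 lie between 127.6 and 545.7.

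Gene counts within a line ranged widely. As 22Rv1 DMSO libraries lay below all its treated ones in nuclear-retained transcripts, its counts are uncertain, and averages against DMSO share this. No averaged fit left this line out. With abiraterone 836 genes passed in C4-2, 991 in LNCaP, 3062 in 22Rv1 and 141 in LNCaP95. Enzalutamide gave 857, 1297, 4549 and 136 in the same order, onvansertib 199, 218, 4530 and 13, abiraterone plus onvansertib 1800, 1302, 4904 and 215, and enzalutamide plus onvansertib 1091, 1041, 5359 and 800. Abiraterone and enzalutamide differed in 296, 690, 232 and 29 genes, and interaction terms passed in 11, 16, 1007 and 3 genes for abiraterone and in 11, 12, 1909 and 3 for enzalutamide. These last counts depended on single libraries. With 1 left out, the difference ranged from 161 to 284, 259 to 945, 81 to 225 and 17 to 41 in that order. The interaction with abiraterone ranged from 4 to 106, 4 to 29, 418 to 1322 and 1 to 13, and that with enzalutamide from 4 to 18, 6 to 19, 1392 to 2118 and 0 to 724. The 106 came without C4-2 DMSO replicate 3, the 418 without 22Rv1 DMSO replicate 1 and the 724 without LNCaP95 enzalutamide-onvansertib replicate 1. In separate fits per line the interactions gave 0, 1, 238 and 0 genes for abiraterone and 0, 2, 1205 and 0 for enzalutamide, the difference gave 68 in 22Rv1 and 15 in LNCaP95, onvansertib gave 131 in C4-2, 107 in LNCaP and 0 in LNCaP95, and LNCaP95 had 83 with enzalutamide and 468 with enzalutamide plus onvansertib. Without the 9 libraries abiraterone gave 1263 genes in C4-2, onvansertib gave 446 in C4-2, 351 in LNCaP, 2888 in 22Rv1 and 54 in LNCaP95, and LNCaP95 had 244 with enzalutamide, 534 with abiraterone plus onvansertib and 147 with enzalutamide plus onvansertib. The difference then gave 787 in C4-2 and 484 in 22Rv1. The interactions gave 28 in C4-2 and 9 in LNCaP for abiraterone and 7 in LNCaP95 for enzalutamide. As no library of C4-2 is among the 9, its counts moved through the spread pooled over lines. Omitting 22Rv1 DMSO replicate 1 gave 2005 genes for abiraterone and 2954 for onvansertib in 22Rv1. In C4-2 the onvansertib count was 326 without DMSO replicate 3 and 120 without onvansertib replicate 2, and in LNCaP the enzalutamide count was 843 without enzalutamide replicate 3. In LNCaP95 the abiraterone count was 81 to 87 without abiraterone replicate 3 or any DMSO replicate. The enzalutamide count was 70 without enzalutamide replicate 1. The onvansertib count was 1 to 7 without DMSO replicate 2 or 3 or onvansertib replicate 3, and 68 or 72 without onvansertib replicate 1 or 2. There the combination with abiraterone gave 126 to 137 without DMSO replicate 2 or 3 or combination replicate 1 or 2. That with enzalutamide gave 218 to 477 without DMSO replicate 1 or 3 or combination replicate 2 or 3, and 2283 without combination replicate 1.

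**Figure D3:**
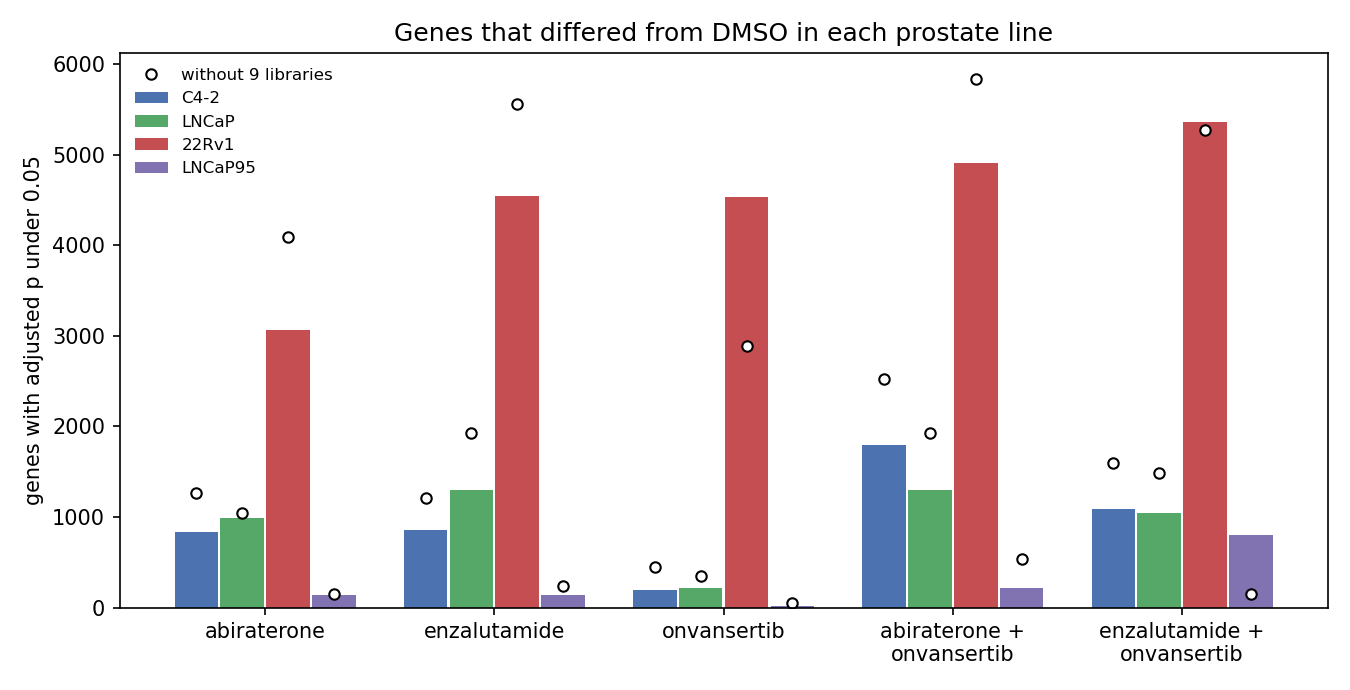
Number of genes with an adjusted p below 0.05 against DMSO (bars) in each prostate line and treatment, with open points for the count without the 9 libraries that stood apart. The bars of 22Rv1 reach from 3062 to 5359 genes and those of LNCaP95 from 13 to 800.

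The abiraterone effect on 14 of the 27 gene lists differed between the 4 prostate lines by the F test. The mean effect on androgen receptor target genes was -1.17 in C4-2, -1.20 in LNCaP, -0.34 in 22Rv1 and -0.08 in LNCaP95 (SE 0.0564, adjusted p = 5.4e-20). Over the 32 members measured in both sets of lines the LNCaP95 mean was 0.012, so its sign depended on the members used. Cholesterol biosynthesis genes ran in another order, with -0.15 in C4-2, -0.45 in LNCaP, -0.83 in 22Rv1 and -0.31 in LNCaP95 (SE 0.0479, adjusted p = 9.3e-12). Integrated stress response genes had 0.18, 0.27, 0.04 and 0.54 (SE 0.0433, adjusted p = 5.8e-09). INSIG1 fell in LNCaP (-0.88 ± 0.056), 22Rv1 (-1.36) and LNCaP95 (-0.97), and its value in C4-2 was -0.15 (adjusted p = 0.13). HMGCS1 fell in 22Rv1 (-1.59 ± 0.071) and LNCaP (-0.62). Doses of abiraterone differed between LNCaP95 and the other lines, so line and dose were not separate there. The 22Rv1 values rest on its DMSO libraries, low in nuclear-retained transcripts, so their place among the lines is uncertain.

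**Figure D4:**
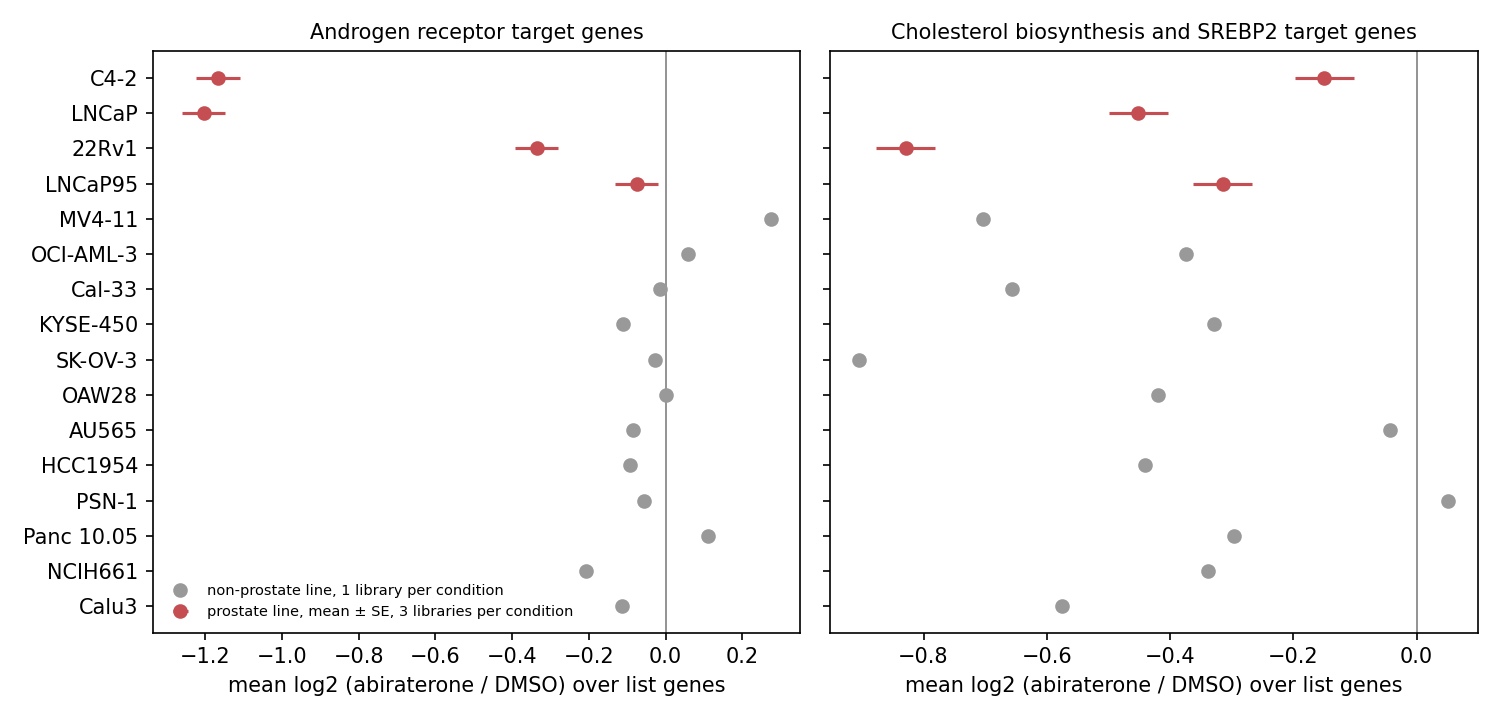
Mean log2 ratio of abiraterone to DMSO over the androgen receptor and SREBP2 target lists per cell line, ± SE from 3 libraries per condition for prostate lines and in grey from 1 per condition for the other 12. For the androgen receptor list, prostate points hold all members measured there and grey points the 32 in both sets. On these the prostate values run from -1.03 to 0.01. C4-2 (-1.17) and LNCaP (-1.20) are the lowest prostate points for it, and 22Rv1 (-0.83) for SREBP2.

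In the 12 non-prostate lines abiraterone was compared with DMSO across lines, with the line as the replicate. Cholesterol biosynthesis and SREBP2 target genes fell, with 11 of 29 lower and 0 higher (22 adjusted over the list alone, median -0.42, adjusted p = 2.4e-06). SQLE (chromosome 8, 124998497 to 125022283) fell by 0.58 ± 0.072 (adjusted p = 2.5e-05) and was lower in 12 of 12 lines. MSMO1 (-0.79 ± 0.106), the acetyltransferase gene ACAT2 (-0.46 ± 0.069) and FDFT1 (-0.54 ± 0.094) also fell, each lower in 12 of 12. IDI1 (-0.64 ± 0.09) and the reductase gene DHCR7 (-0.60 ± 0.111) fell, each lower in 11 of 12. INSIG1 (-0.91 ± 0.158) and HMGCS1 (-0.58 ± 0.11) fell too, but did not pass without the 2 leukaemia lines. The AP-1 gene FOSL1 rose by 0.69 ± 0.125 (adjusted p = 0.0064, higher in 12 of 12 lines), and NF-kB genes rose on balance (0 of 22, 4 adjusted over the list alone, adjusted p = 0.0019). The p53 target list rose on balance (0 of 31, 0 adjusted over the list alone, adjusted p = 0.00041). Fatty acid synthesis genes fell (2 of 19 lower, 4 adjusted over the list alone, adjusted p = 0.15 with an estimated correlation) and immediate early genes rose (1 of 24, 5 adjusted over the list alone, adjusted p = 0.072 with an estimated correlation). Androgen receptor targets did not pass (median -0.01, adjusted p = 0.49). In all, 39 genes passed, 15 higher and 24 lower, with 23 without HCC1954 and 13 without the leukaemia lines.

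Onvansertib alone in the non-prostate lines was followed by a rise of mitotic spindle genes as a list, with 0 of 58 past the threshold over all genes and 32 higher when adjusted over the list alone (median 0.14, adjusted p = 0.002). AURKA (0.25 ± 0.052), SGO2 (0.27 ± 0.054) and CKAP2 (0.24 ± 0.048) had adjusted p-values of 0.066 and were higher in 11, 11 and 12 of 12 lines. Lysosome genes fell as a list (0 of 28, 0 adjusted over the list alone, adjusted p = 0.038, adjusted p = 0.25 with an estimated correlation), a call lost at 0.056 after median-ratio rescaling. Across all genes 1 passed, the actin regulator gene BRK1 (-0.15 ± 0.026, adjusted p = 0.042, lower in 11 of 12 lines), and 1341 had an unadjusted p below 0.05. BRK1 did not pass without OCI-AML-3, Cal-33, KYSE-450, OAW28, HCC1954, PSN-1 or Panc1005 (adjusted p from 0.063 to 0.14). With single lines left out the count lay between 0 and 9, the latter without MV4-11, and edgeR gave 0.

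Abiraterone plus onvansertib in the non-prostate lines changed 765 genes, 360 higher and 405 lower, with 411 without Cal-33. Mitotic spindle genes rose (42 of 58, 47 higher and 3 lower adjusted over the list alone, median 0.26, adjusted p = 1.5e-06), KIF14 at 0.46 ± 0.05 and AURKA at 0.44 ± 0.052, each higher in 12 of 12 lines. DNA replication genes fell (16 of 52, 26 adjusted over the list alone, adjusted p = 0.00058, adjusted p = 0.068 with an estimated correlation), UNG at -0.52 ± 0.06 and MCM6 at -0.43 ± 0.056. Cholesterol biosynthesis genes fell (17 of 29 lower and 1 higher, 23 and 1 adjusted over the list alone, adjusted p = 2.2e-06). INSIG1 (-1.01 ± 0.158), FDFT1 (-0.68 ± 0.094) and the mevalonate kinase gene MVK (-0.61 ± 0.107) were among them. NF-kB genes rose (5 of 22, 6 adjusted over the list alone, adjusted p = 4.7e-05), with the NF-kB regulator gene TNFAIP3 at 0.95 ± 0.185. FAM222A (-0.68 ± 0.112) and the glycolysis gene GAPDH (-0.15 ± 0.026) fell, and FOSL1 (0.77 ± 0.125), BAG3 (0.28 ± 0.04) and SLC7A11 (0.44 ± 0.09) rose. The monooxygenase gene CYP1A1 rose (1.49 ± 0.362, higher in 10 of 12 lines) but did not pass without the leukaemia lines. Fatty acid synthesis genes (6 of 19, 7 adjusted over the list alone, adjusted p = 0.089 with an estimated correlation), lysosome genes (6 of 28, 7 adjusted over the list alone, 0.17) and ribosomal protein genes (3 of 37, 26 adjusted over the list alone, 0.34) fell. Heat shock genes rose (3 of 18, also 3 adjusted over the list alone, 0.34 with an estimated correlation), and p53 targets rose (2 of 31, 3 adjusted over the list alone, 0.34) with a median of -0.01 and a mean of 0.05, which differ in sign. The interaction of abiraterone and onvansertib gave 0 genes by limma, 734 at an unadjusted p below 0.05 and 0 by edgeR.

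The abiraterone effect on lists was compared between the 4 prostate and the 12 non-prostate lines. Androgen receptor target genes had a mean effect of -0.59 ± 0.519 in prostate lines and -0.02 ± 0.126 in the others (SD over lines, 32 members in both sets). The exact permutation test gave p = 0.0066, or 0.141 after adjustment over the lists, and 3 lists had an unadjusted p below 0.05, so no list passed. With the median over members in place of the mean, androgen receptor targets and luminal markers passed (adjusted p = 0.0445 each). Cholesterol biosynthesis genes had means of -0.44 ± 0.289 and -0.42 ± 0.268 (exact permutation p = 0.92).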

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

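The comparison of nuclear-retained transcripts in 22Rv1 was chosen after the data had been seen, while the tests of differences between lines were planned. The F test flagged 14 gene lists because their response to abiraterone differed between the 4 prostate lines, and the means that follow are in the order C4-2, LNCaP, 22Rv1 and LNCaP95. Androgen receptor target genes had -1.17, -1.20, -0.34 and -0.08 (adjusted p = 5.4e-20), and luminal prostate markers -1.01, -1.06, -0.28 and -0.16 (adjusted p = 3.9e-14). Cholesterol biosynthesis genes had -0.15, -0.45, -0.83 and -0.31 (adjusted p = 9.3e-12), and fatty acid synthesis genes 0.08, -0.14, -0.33 and -0.29 (adjusted p = 7.1e-05). Unfolded protein response genes had -0.27, -0.02, -0.20 and 0.14 (adjusted p = 4.1e-15), and integrated stress response genes 0.18, 0.27, 0.04 and 0.54 (adjusted p = 5.8e-09). Steroid metabolism genes had 0.20, 0.08, -0.32 and -0.13 (adjusted p = 5.1e-05), interferon-stimulated genes 0.31, 0.31, 0.02 and 0.04 (adjusted p = 0.00023), and aryl hydrocarbon receptor targets 1.195, -0.29, 0.96 and 0.10 (adjusted p = 0.00042). Mitotic spindle genes had 0.17, 0.03, -0.05 and 0.10 (adjusted p = 0.0047), cytoskeleton genes 0.01, 0.10, -0.07 and -0.28 (adjusted p = 0.0056), and DNA replication genes -0.01, -0.16, -0.10 and -0.12 (adjusted p = 0.0058). Ribosomal protein genes had -0.07, 0.04, -0.29 and -0.07 (adjusted p = 0.0096), and lysosome genes 0.01, 0.09, -0.14 and -0.04 (adjusted p = 0.023). As many lists were called in 3 of 100 splits, the real one included (14, highest other 14). This share is below 0.05 for the count, but does not tell which lists differ beyond chance.

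In 22Rv1, 20 nuclear-retained transcripts had higher medians in every treated group than in DMSO, at 0.66 with abiraterone, 0.83 with enzalutamide, 0.95 with onvansertib, 0.93 with abiraterone plus onvansertib and 1.04 with enzalutamide plus onvansertib, against -0.26 to 0.23 in the other lines. Removing the trend with GC content, length and mean level left a median of 0.85, against 0.88 before (bootstrap SD 0.118), which argues against such a bias as the whole cause. A property of the 3 DMSO libraries cannot be told apart from a drug effect, because they are the only control of this line. Levels differed among the 5 treated groups (F = 3.04, permutation p = 0.018), which such a property alone would not give. But 3 of the 15 treated libraries stood apart, and without them onvansertib has a lone library. Whether the difference rests on these 3 cannot be told. A shared response of 22Rv1 to the drugs stays open as an untested biological explanation.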

How the results depend on the processing

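The fits without the 9 or 7 libraries that stood apart, with a term for the 7, and with edgeR were chosen after seeing the data, and the other alternatives were planned. Counts averaged over lines stayed within 1.5 times of those reported apart from the values below, and the cause was not tested except where fewer samples show it. The abiraterone-onvansertib interaction (29 genes) had 18 with no filter, 82 at a mean of at least 50, 17 after quantile normalisation, 92 without the 7 libraries, 52 with a term for them and 71 with edgeR. Its share of higher calls was 24.1%, against 39.5% after median-ratio rescaling, 11.8% after quantile normalisation, 56.5% without the 9 libraries, 48.9% without the 7 and 36.5% with the term. The enzalutamide-onvansertib interaction (85 genes, 20.0% higher) had 53 after quantile normalisation, 26 (42.3% higher) without the 9 libraries, 42 (40.5%) without the 7 and 564 (282 higher) with the term, and the difference of abiraterone and enzalutamide (491) had 1195 with the term. With cell lines as replicates the counts were 18 for abiraterone, 0 for enzalutamide, 1 for onvansertib, 907 and 551 for the combinations, and 0 for both interactions and for the difference. Onvansertib in prostate lines had 51.5% of calls higher, and 61.6% with edgeR. In non-prostate lines abiraterone (39, 38.5% higher) had 13 (23.1%) without the leukaemia lines and 24.1% higher with no filter, and onvansertib (1) had 0 with no filter, median-ratio rescaling, quantile normalisation, robust moderation, edgeR and without the leukaemia lines. With an estimated correlation 60 list calls of 108 remained in prostate lines and 7 of 16 in the others, and with the median over members 2 lists differed between prostate and non-prostate lines, against 0. After quantile normalisation RPL19 (0.03) and RPS11 (0.01) with enzalutamide, ACTB (0.03) with onvansertib, and RPL14 (0.02), RPS11 (0.02) and RPL19 (0.08) with abiraterone plus onvansertib changed sign. Of 575 averaged values of named genes, 103 no longer passed after quantile normalisation, 48 without the 9 libraries, 45 with no filter, 128, 152 and 139 without replicate 1, 2 or 3 and 476 with cell lines as replicates, of 104 non-prostate values 35 no longer passed without the leukaemia lines and 27 with no filter, and of 46 single-line values 20 no longer passed in a separate fit per line. In 22Rv1 with onvansertib ITGB1P1 (-5.20) turned to 0.21 without the 7 or 9 libraries and 0.28 with the term, and SSX2B (-3.44), uncertain as a close copy of SSX2, turned to 0.37 without the 7 or 9. With a replicate or library left out, the ranges were 1621 to 3145 for abiraterone, 1295 to 2619 for enzalutamide, 1248 to 2482 for onvansertib, 3260 to 4769 and 3034 to 5116 for the combinations, 0 to 183 and 2 to 222 for the interactions and 92 to 577 for the difference. In non-prostate lines they were 23 to 45 for abiraterone, 0 to 9 for onvansertib, 411 to 945 for the combination and 0 for the interaction, and a lone library left in a group was assumed to vary like the other groups. With the replicate number as a block the prostate counts were 3027, 2459, 2315, 4729, 4674, 28, 75 and 438, and 108 lists (1 lost and 1 gained), but same-numbered libraries did not deviate together (mean correlations from -0.0233 to 0.0241), and only 4, 4, 1 and 10 of 18 libraries correlated best with their own number. At a lowest depth of 7.37 M reads, changes in genes of low level can be missed.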

Other observations

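The tests of depth in the 7 libraries and the 3 tests of 22Rv1 transcripts in LNCaP95 were chosen after the result was seen. Single prostate lines differed in how many members of a list moved with abiraterone. Of the 38 androgen receptor targets 29 fell in C4-2, 27 in LNCaP, 17 in 22Rv1 and 4 in LNCaP95, the last with an adjusted p of 0.006 (0.053 with an estimated correlation). NKX3-1 fell in C4-2 (-2.30 ± 0.053), LNCaP (-2.55), 22Rv1 (-0.56) and LNCaP95 (-0.37, adjusted p = 2.5e-06). KLK3, at DMSO means of 34140 normalised reads in C4-2, 11980 in LNCaP, 48.78 in 22Rv1 and 274.3 in LNCaP95, fell in C4-2 (-1.64 ± 0.127) and LNCaP (-2.20). With enzalutamide NKX3-1 fell in C4-2 (-2.97), LNCaP (-2.85) and 22Rv1 (-0.46), and its value in LNCaP95 was -0.01 (adjusted p = 1). Integrated stress response genes rose with abiraterone in 22 of 36 members in LNCaP95 (adjusted p = 2.5e-19), 15 in LNCaP and 6 in C4-2, while in 22Rv1 6 rose and 9 fell (adjusted p = 0.76, with a median of -0.03 and a mean of 0.04). Cholesterol biosynthesis genes fell in 7 of 28 members in C4-2, 20 in LNCaP, 21 in 22Rv1 and 14 in LNCaP95.

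Of 16794 genes, 6410 differed in the 7 libraries with ITGB1P1 at 0. Of 241 processed pseudogenes 26.1% differed, against 8.30 to 20.3% of matched coding genes in 1000 draws, as reads assigned to other genes could give. But in each of the 7 ITGB1 exceeded its group by more than ITGB1P1 held elsewhere (at most 545.7). Such moves are thus not the whole cause. Removing the GC trend left 4957 genes (3843 shared), which argues against GC bias as the whole cause. Correlations with GC were -0.49 to -0.17 in the 7 (others -0.30 to 0.39), so a part stays open. Of the 7, 2 lay below the median depth of their line's others and the rest above. This argues against a 1-sided depth shift. A difference in preparation or read processing stays open, as the labels name none, and no biological explanation was tested.

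LNCaP95 onvansertib replicate 3 held transcripts that mark 22Rv1. The median share of 85 such markers was 1.57% of the 22Rv1 level, and 89.4% of them lay within 2-fold of it, as RNA or reads of 22Rv1 in this library would give. Markers of the 12 non-prostate lines had a highest median of 0 in it, which argues against these lines as their source. C4-2 and LNCaP had too few markers of their own for that test, but 68.2% of the 22Rv1 markers had a lower level in both of them than in this library, which argues against either as the whole source. Whether the transfer was of RNA, of cells or of index reads stays open.

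Other splits of the prostate samples were counted for each averaged comparison, 100 in number with the real one included. Only the real split gave as many genes for abiraterone (3084, highest other 940), enzalutamide (2510, 2150) and onvansertib (2340, 1101). The same held for abiraterone plus onvansertib (4796, 2530), enzalutamide plus onvansertib (4721, 3392) and the difference of abiraterone and enzalutamide (491, 171). Chance alone is excluded for these. For the abiraterone-onvansertib interaction 4 splits gave as many (29, highest other 181), and 5 did for enzalutamide-onvansertib (85, highest other 496). In both, other splits called several times the real count. Libraries exchanged between treatments can carry main effects along, so these splits cannot decide and chance is excluded for neither. A structure of the samples could raise the counts too, and the cause was not tested. For list calls 1 split gave as many in prostate lines (108, highest other 7) and 1 in non-prostate lines (16, highest other 1). In non-prostate lines 1 split gave as many genes for abiraterone (39, highest other 1) and 1 for the combination (765, highest other 66). Chance alone is excluded for these. For onvansertib 3 did (1, highest other 1), but 1 gene cannot exclude chance. For the interaction (0, highest other 1) all 100 splits did by construction, and nothing was tested.

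Within single lines 3 libraries against 3 make 10 splits, too few for a share under 0.05, and values follow in the order C4-2, LNCaP, 22Rv1 and LNCaP95. In all but 1 of these comparisons 1 split, the real one, gave as many genes, and for onvansertib in LNCaP95 4 splits did. Abiraterone had 836, 991, 3062 and 141 genes (highest other 51, 62, 193 and 7), enzalutamide 857, 1297, 4549 and 136 (18, 92, 30 and 4) and onvansertib 199, 218, 4530 and 13 (21, 19, 650 and 31). Abiraterone plus onvansertib had 1800, 1302, 4904 and 215 (138, 31, 39 and 3), enzalutamide plus onvansertib 1091, 1041, 5359 and 800 (31, 18, 1942 and 9), and the difference of abiraterone and enzalutamide 296, 690, 232 and 29 (10, 54, 11 and 10). Interactions within a line had 100 splits. As many genes as for abiraterone and onvansertib (11, 16, 1007 and 3) came from 55, 46, 12 and 53 splits (highest other 823, 671, 2884 and 107). As many as for enzalutamide and onvansertib (11, 12, 1909 and 3) came from 35, 48, 19 and 53 (highest other 573, 1013, 3581 and 401). Chance is not excluded for these, and what raised the counts in other splits was not tested.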
